A study of Rattus norvegicus with 4 samples.

How the data were processed

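Total RNA of 4 samples of cultured rat aortic smooth muscle cells, 2 with vehicle and 2 with IL-1b, was labelled with biotin and hybridised to single-colour Affymetrix rat arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale made with MAS5, per the submitters' processing notes, and the MAS5 version and settings are not given in the sources used here. MAS5 subtracts background, summarises the probes of a set and scales each array. In the values themselves, the mean of each array without the lowest and highest 2% of probe sets was 250.0, so no further normalization was applied. The deposited table used here holds intensities without detection calls, so no probe set could be called present or absent by the authors' processing. Scaling by a trimmed mean fixes only the general level of an array, and an array with weaker signal has its background raised with the rest.

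An offset of 5.49 intensity units, the 10th percentile of all values, was added before log2, because MAS5 values of dim probe sets are noisy. All log2 fold changes and fitted folds are on this offset scale, which understates the change of dim genes. The 57 control probe sets were left out, and probe sets were kept when their mean log2 value over the 4 arrays was at or above the 40th percentile (5.37). The 18625 probe sets left were fitted with limma 3.58.1 in R 4.3.3, using lmFit on group means and eBayes with an intensity trend, since the spread of MAS5 values depends on brightness. The fit had 2 residual degrees of freedom per probe set and 4.91 from the prior. Adjusted p values are Benjamini-Hochberg values over all probe sets tested, with 0.05 as the threshold, and every adjusted p of a gene comes from limma.

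Gene symbols came from the platform annotation, in which 20826 non-control probe sets had 1 symbol, 436 had several and 9780 were not listed and are unnamed here. Of the probe sets with 1 symbol, 99.7% matched a current gene by its identifier, and 0 symbols changed. No gene was named from a probe set with several symbols. A gene was represented by its brightest probe set with 1 symbol, which gave 10000 genes. Of these, 2926 had several probe sets tested, and disagreements in direction were counted.

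A set of 27 gene lists was fixed before the data were examined, and the 26 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Each list was also tested with fry and with an estimated correlation, for which camera has only the fit's 2 residual degrees of freedom. Genes named in the text were taken by a rule fixed at the same time. It takes the 15 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap, 21 genes chosen for smooth muscle and inflammation, and up to 4 members of each list with the largest change past the threshold. Symbols that are only provisional locus names were left out of the largest changes. Members that went against their list, and others so marked, were named after their values were seen.

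As a bound on folds of dim genes, added after the data were examined, the background of each array was taken as the 95th percentile of 27 control probe sets for bacterial transcripts that read dim on every array. It was 29.4 and 26.9 on the vehicle arrays and 76.7 and 18.8 on IL-1b replicates 1 and 2. The share of other probe sets above it was 67.4%, 65.2%, 54.2% and 72.3%, in the same order. A gene below background on both arrays of a group was given the ratio of the brighter group's geometric mean to the higher of background and the gene's own value, written as at least so many fold.

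The number of arrays limits the precision. The procedure was tested on simulated data of the same size, with 50 of 18625 probe sets changed at each of 4 sizes. For IL-1b against vehicle it recovered 14% of changes of 1 on the log2 scale, 56% of changes of 2, 66% of changes of 3 and 84% of changes of 5, and 3 of 113 calls were false. In a second simulation camera called the 1 list that was moved and 0 of 28 that were not. The first simulation gave 113 calls against 2503 in the data. With fewer calls the adjustment is stricter, so its recovery rates do not carry over to the data. The simulated noise was independent between probe sets and no array stood apart, so the lists not called say nothing about correlated genes.

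Alternatives fixed before the data were examined were no offset, an offset at the 25th percentile, quantile normalization, median centring, no filter, a filter at the 60th percentile, no intensity trend, a robust prior, the replicate number as a block, leaving out each array, at least 2-fold, an adjusted p under 0.01, other choices of the probe set for a gene, and the other list tests. Where an array was left out, the lone sample of its group was assumed to vary like the other group. Added after the data were examined were families of gene symbols, gene groups outside the lists, and list members on each IL-1b array alone. A further alternative and a test of 1 explanation of the interferon result are not reported here.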

Results

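Messenger RNA was measured in aortic smooth muscle cells of Sprague-Dawley rats, the contractile cells of the middle layer of the artery wall, kept in culture. The cells had 5 days in medium with 10% serum and 3 days in medium without serum. For the next 24 hours, 2 samples received interleukin-1 beta (IL-1b), a pro-inflammatory cytokine, at 2.5 ng/mL, and 2 samples received the vehicle, 0.1% bovine serum albumin. The comparison asks which transcripts the cytokine raised or lowered. Each sample was hybridised to its own array with 31099 probe sets, and each array's values had been scaled to the same trimmed mean intensity. The labels number the samples within a group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

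The vehicle arrays correlated with each other at Pearson r = 0.972 over probe sets on the log2 scale, the IL-1b arrays at 0.912, and arrays of different groups at 0.810 to 0.878. No probe set had identical values on any pair of arrays. IL-1b replicate 1 stood apart from the other 3 arrays. Its hybridisation controls, bacterial transcripts added in fixed amounts to every sample, read 3.50 times their mean on the vehicle arrays, against 0.954 times on IL-1b replicate 2. Its median intensity was 89.6, against 66.4 and 61.3 on the vehicle arrays and 61.7 on IL-1b replicate 2. The ratio of 3' to 5' probe sets, a measure of RNA integrity, was 1.57 to 1.96 for actin and 1.04 to 1.32 for Gapdh over the 4 arrays.

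**Figure D1:**
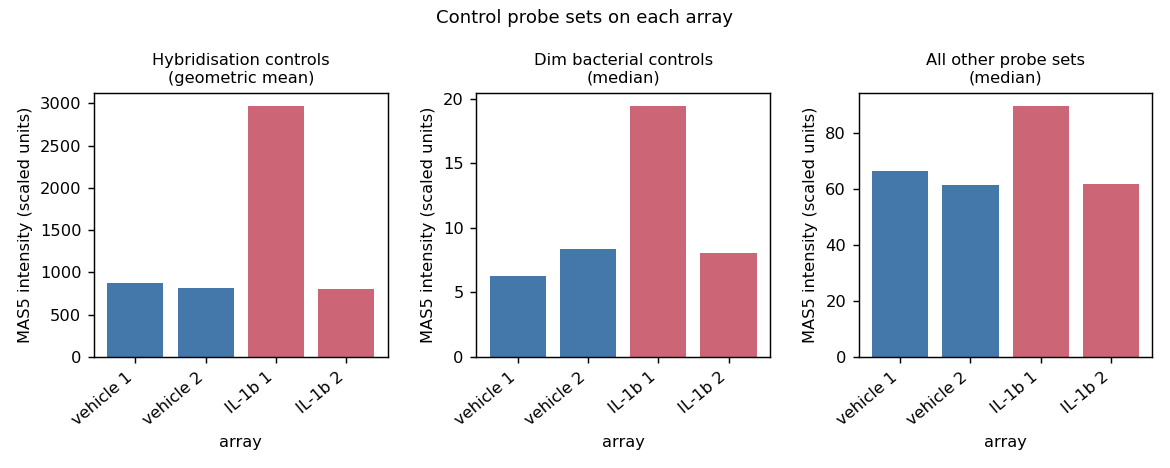
Bars give the MAS5 intensity in scaled units of 3 kinds of probe sets on each of the 4 arrays, as the geometric mean of the hybridisation controls, the median of dim bacterial controls and the median of all other probe sets. IL-1b replicate 1 is the highest bar in each panel, at 2971, 19.4 and 89.6 intensity units.

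After 24 hours with IL-1b, the smooth muscle cells had higher transcript levels of most chemokines measured, of colony-stimulating factors and of several acute phase proteins. The prostaglandin synthases Ptges and Ptgs2 were also higher. Of the measured genes, 17 of 27 of the contractile apparatus, 23 of 33 of the interferon response and 8 of 42 of the cell cycle were lower. No list of genes, higher or lower, kept its call with an estimated correlation. That test had only the fit's 2 residual degrees of freedom, so it was hard for any list to pass after adjustment. Among the largest increases was that of Orm1, which encodes the acute phase protein orosomucoid. Orm1 rose from a mean intensity of 17.2 ± 16.3 to 15504 ± 6481 (SD, n = 2), 758-fold on the offset log2 scale, with 1 of the 2 vehicle arrays above background (adjusted p = 1.0e-04). Without vehicle replicate 1 or 2 its log2 fold change of 9.57 was 8.76 or 10.37. Without vehicle replicate 1 it was below those of Cxcl2 and Pla2g2a, and below the 9.26 of Ccl20 with all arrays. Npr3, the clearance receptor for natriuretic peptides, was among the largest decreases, from 970.0 ± 34.1 to 34.9 ± 33.6 (SD, n = 2), with 1 of the 2 IL-1b arrays above background. Its log2 fold change of -4.90 ± 0.57 (SE, adjusted p = 0.0021) was -3.93 without IL-1b replicate 1 and -5.88 without IL-1b replicate 2. Among the other large increases, Wfdc18 rose at least 59.1-fold, from 4.15 ± 2.42 to 1663 ± 74.6 (adjusted p = 4.9e-05), and the lymphocyte activation antigen Cd69 at least 44.9-fold, from 3.51 ± 2.09 to 1264 ± 88.5 (7.7e-05). Among the other large decreases, the microtubule protein Map2 fell at least 11.5-fold, from 439 ± 46.3 to 11.7 ± 6.37 (6.6e-04), and Mybphl at least 11.3-fold, from 428 ± 8.39 to 12.3 ± 0.0227 (3.9e-04). Crispld2, Slc24a3, Itga11 and Mrgprf, each above background on 1 of the 2 IL-1b arrays, had log2 fold changes of -4.90, -4.64, -4.49 and -4.46.

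Of 10000 genes tested, 1532 passed an adjusted p of 0.05 in limma, 719 of them higher with IL-1b and 813 lower. Among these, 497 were at least 2-fold higher and 560 at least 2-fold lower, and 103 were at least 8-fold higher and 60 at least 8-fold lower. Over the 18625 probe sets tested, 2503 passed, 1178 higher and 1325 lower, and 489 of them carried no gene name here. In all 1532 genes both IL-1b arrays lay on the same side of both vehicle arrays. With 2 arrays in each group the threshold nearly requires this, so it adds no support to the calls. Of 658 genes with several probe sets and at least 1 call, Ap3m1 and Enpep had calls in both directions. Both were named after their values were seen. Among genes named by the fixed rule, 1 of 2 probe sets tested passed for Mylk, Top2a, Nusap1, Pth1r, Plin2, Pdia3 and Tfrc. For Synpo2 and Ncam1 it was 2 of 3. The count of 2503 probe sets became 1487 without vehicle replicate 1, 1357 without vehicle replicate 2, 5423 without IL-1b replicate 1 and 8666 without IL-1b replicate 2. Without the intensity trend of the variance 963 probe sets and 576 genes passed.

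**Figure D2:**
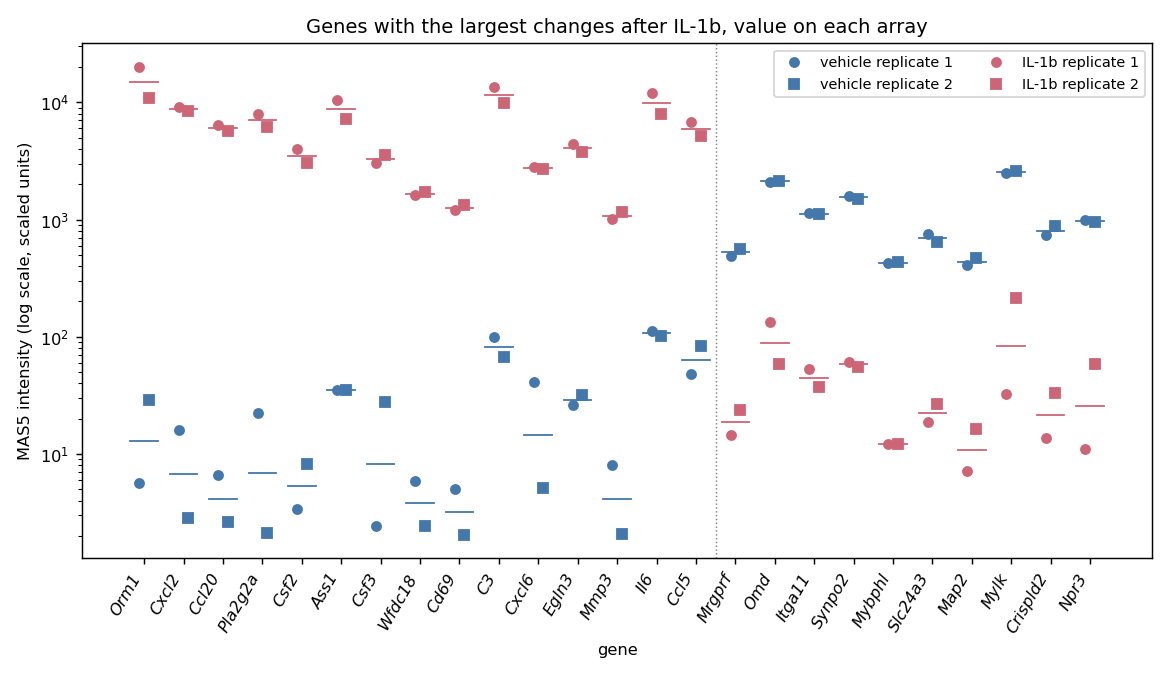
Points give the MAS5 intensity, on a log axis in scaled units, of the 15 genes with the largest increase and the 10 with the largest decrease, with circles for replicate 1, squares for replicate 2 and horizontal lines for the geometric mean of each group. The IL-1b points of Orm1 lie at 20087 and 10921, and those of its vehicle arrays at 5.68 and 28.8.

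Chemokines are secreted proteins that attract leukocytes. Of 18 measured members, 13 rose, 2 fell and 3 did not pass (14 rose and 3 fell adjusted over the list alone), with a median log2 fold change of 3.71, or 2.12 over 24 members with no filter on dim probe sets. Cxcl2, a neutrophil attractant, rose at least 310-fold, from 9.50 ± 9.38 to 8726 ± 530 (SD, n = 2, adjusted p = 5.1e-05). Ccl20 rose at least 215-fold, from 4.61 ± 2.77 to 6058 ± 541 (adjusted p = 2.4e-05). Both were below background on both vehicle arrays, so their folds are lower bounds, and the fitted log2 fold change of Cxcl2 was 10.03 and 8.66 without vehicle replicates 1 and 2. Cxcl6 and Ccl5 rose by 6.94 ± 0.61 and 6.43 ± 0.26 (log2, SE), with Cxcl6 above background on 1 of the 2 vehicle arrays. Its log2 fold change was 8.01 and 5.87 without vehicle replicates 1 and 2. Cxcl1 rose 81.8-fold and Ccl2, which attracts monocytes, 5.84-fold (adjusted p = 1.6e-04 and 0.0082). On IL-1b replicate 1 these read higher than on IL-1b replicate 2, at 29710 against 11426 for Cxcl1 and 36668 against 13965 for Ccl2. The log2 fold change of Ccl2 was 2.55, and 1.85 without IL-1b replicate 1 and 3.24 without IL-1b replicate 2. For Cxcl1 it was 6.35, and 5.66 and 7.04 without these arrays. Without the intensity trend the adjusted p of Ccl2 was 0.078. The 2 members that fell, named after their values were seen, were Cxcl10 and Cxcl13, each with a log2 fold change of -2.17 ± 0.15. Cxcl10 is induced by interferons, and Cxcl13 attracts B cells. Of 2 other chemokines that interferons induce, named after their values were seen, Cxcl9 rose by 2.56 ± 0.22 (adjusted p = 5.0e-04) and Cxcl11 did not pass (log2 fold change 0.39, adjusted p = 0.16). The chemokine list was higher in camera (adjusted p = 1.3e-07), with an adjusted p of 0.25 with an estimated correlation.

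Among 14 measured cytokines, 9 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. With no filter on dim probe sets 9 of 26 rose, and the median log2 fold change of 2.92 was 1.59. The colony-stimulating factor Csf2 (GM-CSF), which drives the growth of granulocytes and macrophages, rose at least 124-fold, from 5.84 ± 3.45 to 3528 ± 716 (SD, n = 2, adjusted p = 3.2e-05). Csf3 (G-CSF) rose 202-fold and was above background on 1 of the 2 vehicle arrays. Its log2 fold change of 7.66 was 6.63 without vehicle replicate 1 and 8.69 without vehicle replicate 2. Il6 rose 87.1-fold, from 107 ± 7.30 to 10002 ± 2868 (adjusted p = 3.2e-05), and Lif at least 32.5-fold, from 13.1 ± 2.36 to 913 ± 22.0 (9.1e-05). The 1 member that fell, named after its value was seen, was Il15, a growth factor of natural killer and memory T cells, at -3.24 ± 0.72 (log2, SE, adjusted p = 0.028). It was above background on 1 of the 2 IL-1b arrays, and at -2.18 and -4.30 without IL-1b replicates 1 and 2. Without either vehicle array 0 cytokines were lower, and without IL-1b replicate 1 there were 2. The cytokine list was higher (camera adjusted p = 2.7e-07; adjusted p = 0.18 with an estimated correlation).

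The NF-kB list, made of subunits of this inflammatory transcription factor and the feedback genes it induces, had 22 of 30 measured members higher, 0 lower and 8 not past the threshold (25 higher adjusted over the list alone). It had the smallest p of the 26 lists tested (camera adjusted p = 3.5e-17; adjusted p = 0.18 with an estimated correlation). Tnfrsf9, a costimulatory receptor, rose at least 41.1-fold, from 9.11 ± 6.09 to 1187 ± 392 (SD, n = 2, adjusted p = 1.8e-04). Without IL-1b replicate 2, 2 members of the list were lower. Map3k8, a kinase upstream of ERK that was above background on 1 of the 2 vehicle arrays, rose by 5.24 ± 0.35 and Tnfaip2 by 5.01 ± 0.20 (log2, SE). Zc3h12a, an RNase that degrades cytokine transcripts, rose by 4.24 ± 0.22. Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, rose 12.4-fold from 311 ± 21.2 to 3913 ± 52.5 (SD, n = 2, adjusted p = 3.2e-05). Within IL-1 receptor signalling, 6 of 20 measured members rose, 2 fell and 12 did not pass, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.084). The receptor Il1r1 rose 15.8-fold, from 165 ± 16.7 to 2681 ± 101 (adjusted p = 3.2e-05), and its 3 probe sets gave log2 fold changes of 3.91 to 3.99. The related receptor Il1rl1, which binds IL-33 and was above background on 1 of the 2 vehicle arrays, rose by 4.67 (log2), or by 5.46 and 3.88 without vehicle replicates 1 and 2. Irak3, an inhibitor of the pathway, rose by 2.99, and Socs3 rose at least 4.36-fold, from 19.7 ± 3.06 to 124 ± 22.9 (adjusted p = 0.029). Socs3 missed the threshold without vehicle replicate 1 or 2 (adjusted p = 0.10 and 0.089). The list itself passed without vehicle replicate 1, vehicle replicate 2 or IL-1b replicate 1 (adjusted p = 0.025, 0.015 and 0.041), and the members lower numbered 6 without IL-1b replicate 2 and 1 without either vehicle array.

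In the complement and acute phase list, 8 of 13 measured members rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.18 with an estimated correlation). With no filter on dim probe sets 8 of 27 members rose and 1 fell. The median log2 fold change was then 0.67, lower than with the filter. Besides Orm1, complement component C3 rose 131-fold, from 84.1 ± 23.0 to 11701 ± 2660 (SD, n = 2, adjusted p = 3.2e-05). Lcn2, which binds bacterial iron carriers, rose by 6.11 ± 0.43 and Lbp, the lipopolysaccharide-binding protein, by 5.13 ± 0.20 (log2, SE). Lcn2 read 40773 on IL-1b replicate 1 and 14561 on IL-1b replicate 2, and its log2 fold change was 5.37 and 6.85 without these arrays in turn. The 1 member that fell, named after its value was seen, was F3, tissue factor, the starter of blood clotting, at -1.21 ± 0.20. Without vehicle replicate 2, 0 members were lower.

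For prostanoid and nitric oxide synthesis, 10 of 16 measured members rose, 1 fell and 5 did not pass (13 rose and 1 fell adjusted over the list alone). The median log2 fold change was 1.43, and 0.67 over 26 members with no filter on dim probe sets, of which 9 rose. Pla2g2a, a secreted phospholipase, rose at least 249-fold, from 12.3 ± 14.4 to 7058 ± 1238 (SD, n = 2, adjusted p = 1.5e-04), and its fitted log2 fold change was 9.85 and 7.97 without vehicle replicates 1 and 2. Ass1, which regenerates arginine, the substrate of nitric oxide synthases, rose 213-fold from 35.3 ± 0.188 to 8837 ± 2221 (adjusted p = 2.4e-05). The prostaglandin synthases Ptges and Ptgs2 (cyclooxygenase 2) rose by 4.38 ± 0.33 and 3.23 ± 0.17 (log2, SE). Ptges2, Ptges3 and Ptgis, named after their values were seen, did not pass (adjusted p = 0.11, 0.52 and 0.13). The 1 member that fell, named after its value was seen, was Pts, an enzyme of tetrahydrobiopterin synthesis, at -1.35 ± 0.22, and without vehicle replicate 2, 0 members were lower. The list was higher (camera adjusted p = 9.9e-08; adjusted p = 0.18 with an estimated correlation). Nos2, the inducible nitric oxide synthase, has no value here, because its 1 probe set with a single symbol was too dim to be tested and another probe set carries several symbols.

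Of 10 measured adhesion molecules, 4 rose, 2 fell and 4 did not pass (6 rose and 2 fell adjusted over the list alone). Vcam1 and Icam1, which bind leukocyte integrins, rose 10.8-fold and 4.89-fold (adjusted p = 1.3e-04 and 1.8e-04). Selp (P-selectin), above background on 1 of the 2 vehicle arrays, rose by 3.21 ± 0.41 and the hyaluronan receptor Cd44 by 2.92 ± 0.14 (log2, SE). Mcam, a marker of vascular mural cells, fell by 2.81, and F11r, a junctional adhesion molecule named after its value was seen, fell by 1.12. The list passed (camera adjusted p = 0.027), with an adjusted p of 0.25 with an estimated correlation, 0.064 without the intensity trend and 0.072 without IL-1b replicate 2. Without either vehicle array 1 member fell, and without IL-1b replicate 2 there were 3.

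Among matrix proteases and their inhibitors, 12 of 28 measured members rose, 5 fell and 11 did not pass (15 rose and 5 fell adjusted over the list alone). The metalloproteinases Mmp3 (stromelysin) and Mmp13 (a collagenase) were below background on both vehicle arrays and rose at least 38.4-fold and at least 24.4-fold, to 1081 ± 96.6 from 5.09 ± 4.27 and to 689.7 ± 112 from 2.68 ± 0.770 (SD, n = 2, adjusted p = 1.4e-04 and 2.0e-04). The aggrecanase Adamts4 rose at least 18.1-fold, from 18.7 ± 1.65 to 519 ± 133 (3.6e-04). Plat, tissue plasminogen activator, rose by 4.42 ± 0.36 (log2, SE, adjusted p = 3.9e-04), or by 3.83 and 5.01 without IL-1b replicates 1 and 2. The members that fell, named after their values were seen, were Mmp11, Adamts9, Adamts1, Timp3 and Mmp23, at -2.42 to -1.12. The list was near the threshold (camera adjusted p = 0.046), with 0.25 as the adjusted p with an estimated correlation, and 0.059 and 0.068 without IL-1b replicates 1 and 2, and 8 members were lower without IL-1b replicate 1. The probe sets of Mmp9 with a single symbol were too dim to be tested.

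Structural matrix proteins moved in both directions, with 9 of 52 measured members higher, 11 lower and 32 not past the threshold (14 higher and 13 lower adjusted over the list alone). The list did not pass (camera adjusted p = 0.43), and camera put it higher and fry lower. Ogn (osteoglycin) fell by 2.64 ± 0.17, the fibrillar collagen chain Col11a1 by 2.55 ± 0.13 and Fbln5, needed for elastic fibre assembly, by 2.27 ± 0.14 (log2, SE). Vcan (versican), a large proteoglycan, rose by 2.27 ± 0.17. Elastin, Eln, fell by 1.33 ± 0.23 at its brightest probe set, which missed the threshold without the intensity trend (adjusted p = 0.081). Its other probe set gave a log2 fold change of -4.26. For Col1a1, the main collagen chain, the values at its brightest probe set were 13590 ± 229 and 16369 ± 5518 (SD, n = 2, adjusted p = 0.64). The other probe set of Col1a1 did not pass either, at a log2 fold change of 0.44 (adjusted p = 0.46). On IL-1b replicate 1 Col1a1 read 20271, and on IL-1b replicate 2 it read 12467. Its log2 fold change of 0.23 was -0.12 under quantile normalization and also without IL-1b replicate 1, and was 0.58 past the threshold without IL-1b replicate 2. The list's median of 0.21 was -0.04 without IL-1b replicate 1, and without IL-1b replicate 2 it passed (adjusted p = 0.0061) with 29 members higher and 14 lower. Without IL-1b replicate 1 there were 14 higher and 19 lower, and without vehicle replicates 1 and 2 there were 3 higher each and 8 and 7 lower.

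The smooth muscle contractile list holds the actin, myosin and linker proteins by which differentiated smooth muscle is recognised. Of 27 measured members, 17 fell, 2 rose and 8 did not pass (21 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -1.26. Without the intensity trend 8 fell, and without either vehicle array 13 fell. The list was lower (camera adjusted p = 1.2e-07), with an adjusted p of 0.25 with an estimated correlation. Acta2, smooth muscle alpha-actin, fell 3.15-fold, from 12767 ± 379 to 4139 ± 1209 (SD, n = 2, adjusted p = 0.0045). Cnn1 (calponin) fell 7.44-fold from 3466 ± 352 to 467 ± 113 (adjusted p = 2.1e-04). Tagln (SM22-alpha) fell by 1.19 ± 0.18 and the smooth muscle myosin heavy chain Myh11 by 0.82 ± 0.19 (log2, SE). Synpo2, an actin-bundling protein, fell by 4.60 ± 0.18 and was above background on 1 of the 2 IL-1b arrays, and Lmod1, an actin nucleator of smooth muscle, by 3.54 ± 0.29. Ldb3 fell at least 9.03-fold, from 344 ± 32.8 to 28.3 ± 22.8 (adjusted p = 0.0055), being below background on both IL-1b arrays. Mylk, myosin light chain kinase, fell by 4.80 ± 0.70 at its brightest probe set, and its other probe set did not pass. The brightest read 32.3, below background, on IL-1b replicate 1 and 215 on IL-1b replicate 2. Its log2 fold change was -3.53 without IL-1b replicate 1 and -6.07 without IL-1b replicate 2, and that fitted for Ldb3 was -4.30 and -2.80. The 2 members that rose, named after their values were seen, were the integrin subunits Itga5 and Itga7, at 2.34 ± 0.14 and 1.27 ± 0.16. Myh11 and Tagln missed the threshold without vehicle replicate 1 (adjusted p = 0.19 and 0.080) or vehicle replicate 2 (0.42 and 0.10). Without the intensity trend Acta2, Tagln, Myh11, Mylk and Ldb3 had adjusted p values of 0.056, 0.054, 0.10, 0.068 and 0.050.

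Among the transcriptional regulators of these genes, 8 of 23 measured members fell, 2 rose and 13 did not pass (11 fell and 4 rose adjusted over the list alone), and the list did not pass (camera adjusted p = 0.12). Myocd (myocardin), the coactivator that drives contractile genes with serum response factor, fell 12.9-fold, from 868 ± 141 to 62.4 ± 12.1 (SD, n = 2, adjusted p = 1.8e-04), with 1 of the 2 IL-1b arrays above background. Klf4, a repressor of contractile genes, rose 10.2-fold, from 94.0 ± 1.25 to 1053 ± 424 (adjusted p = 5.1e-04). The DNA demethylase Tet2 fell by 1.46 ± 0.30 and the Notch ligand Jag1 by 1.36 ± 0.16 (log2, SE), and Tet2 had an adjusted p of 0.10 without the intensity trend. The other member that rose, named after its value was seen, was the histone demethylase Kdm6b, at 0.80 ± 0.18. Calls in both directions became fewer without a vehicle array and more numerous without an IL-1b array. The list's median of -0.50 was -0.54 and -0.47 without vehicle replicates 1 and 2, and -0.33 and -0.27 without IL-1b replicates 1 and 2.

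Interferons, the antiviral cytokines, induce a wide set of defence genes. Of 33 measured members of the interferon response list, 23 fell, 0 rose and 10 did not pass (27 fell adjusted over the list alone), with a median log2 fold change of -1.32, and 14 fell without the intensity trend. The antiviral GTPases Mx1 and Mx2 fell by 2.87 ± 0.16 and 2.71 ± 0.15 (log2, SE), from 3490 ± 121 to 477 ± 70.2 for Mx1 (SD, n = 2, adjusted p = 1.1e-04). Igtp, an interferon-inducible GTPase, and Ifit3, which restrains viral translation, had log2 fold changes of -2.84 ± 0.25 and -2.80 ± 0.22. The list was lower (camera adjusted p = 7.7e-16; adjusted p = 0.18 with an estimated correlation). On IL-1b replicate 1, whose controls stood apart, 31 of the 33 members lay below both vehicle arrays, and on IL-1b replicate 2 there were 32. In class I antigen presentation, 2 of 14 measured members rose, 2 fell and 10 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.74). The immunoproteasome subunits Psmb8 and Psmb9 fell by 1.06 ± 0.21 and 0.79 ± 0.14. The proteasome activator subunit Psme2 and the disulfide isomerase Pdia3 rose by 0.60 ± 0.15 and 0.66 ± 0.17. None of these 4 passed without vehicle replicate 1 (adjusted p = 0.059, 0.15, 0.52 and 0.55, in that order), without vehicle replicate 2 (0.057, 0.18, 0.50 and 0.51) or without the intensity trend (0.11, 0.095, 0.16 and 0.15). Pdia3 also missed the threshold under median centring (adjusted p = 0.054), and both Pdia3 and Psme2 with no filter (0.071 and 0.061) and with the replicate number as a block (0.057 each). Without IL-1b replicates 1 and 2 there were 5 and 7 members higher and 4 and 6 lower.

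**Figure D3:**
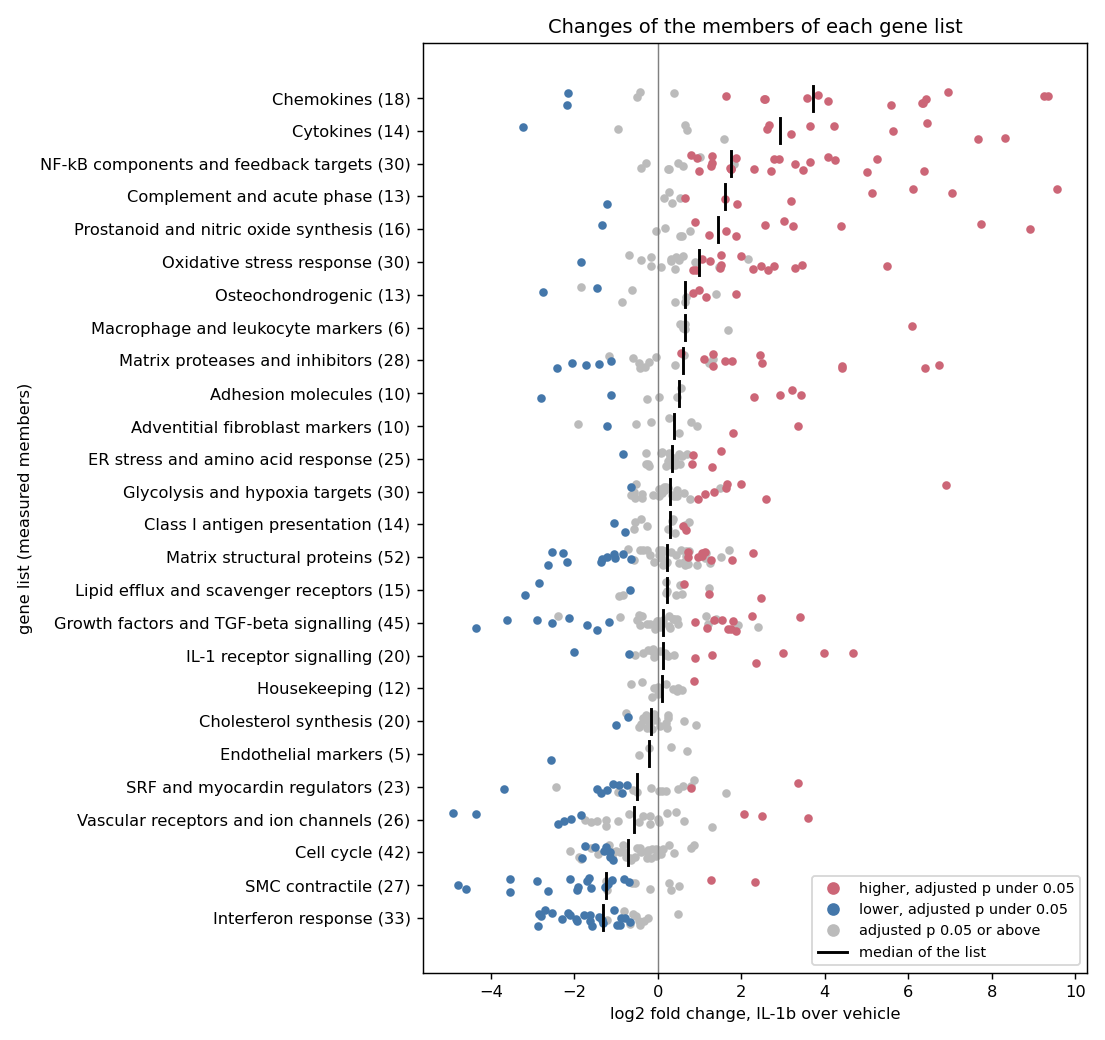
Each point is the log2 fold change, IL-1b over vehicle, of 1 measured member of a gene list fixed before the data were examined, coloured by whether it passed an adjusted p of 0.05 and in which direction. Short vertical lines are the medians, from 3.71 for chemokines to -1.32 for the interferon response.

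Of 42 measured cell cycle genes, 8 fell, 0 rose and 34 did not pass, the same adjusted over the list alone, with a median log2 fold change of -0.72 (camera adjusted p = 2.6e-04; adjusted p = 0.25 with an estimated correlation). The DNA topoisomerase Top2a fell by 1.82 ± 0.28, the cytokinesis factor Ect2 by 1.75 ± 0.39, the mitotic kinesin Kif20a by 1.51 ± 0.35 and the spindle protein Nusap1 by 1.30 ± 0.29 (log2, SE). Top2a and Ect2 were above background on 1 of the 2 IL-1b arrays. None of these 4 passed without vehicle replicate 1 (adjusted p = 0.094, 0.24, 0.15 and 0.25), and Ect2, Kif20a and Nusap1 also missed the threshold without vehicle replicate 2 (0.12, 0.073 and 0.16) and without the intensity trend (0.075, 0.11 and 0.069). Members lower numbered 1 without either vehicle array, 22 without IL-1b replicate 1 and 21 without IL-1b replicate 2.

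In the oxidative stress list, 15 of 30 measured members rose, 1 fell and 14 did not pass (16 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.3e-08; adjusted p = 0.18 with an estimated correlation). Slc7a11, the cystine importer for glutathione synthesis, rose by 5.49 ± 0.28, the metallothionein Mt2A by 3.45 ± 0.35 and Nox1, a superoxide-producing oxidase, by 2.78 ± 0.29 (log2, SE). Slc7a11 was above background on 1 of the 2 vehicle arrays. Sod2, mitochondrial superoxide dismutase, rose 9.71-fold from 1256 ± 54.1 to 12719 ± 4899 (SD, n = 2, adjusted p = 3.9e-04). The 1 member that fell, named after its value was seen, was the glutathione transferase Gsta4, above background on 1 of the 2 IL-1b arrays, at -1.85 ± 0.29, and members lower numbered 0 without either vehicle array and 2 without either IL-1b array. Of 30 measured genes of glycolysis and hypoxia, 8 rose, 1 fell and 21 did not pass (11 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0055; adjusted p = 0.27 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, rose 119-fold, from 28.8 ± 3.93 to 4078 ± 483, with 1 of the 2 vehicle arrays above background. The vasodilator peptide Adm rose by 2.59 ± 0.32, and the glucose transporters Slc2a3 and Slc2a1 by 1.99 ± 0.16 and 1.65 ± 0.15. The 1 member that fell, named after its value was seen, was the collagen prolyl hydroxylase P4ha1, at -0.63 ± 0.14. Without IL-1b replicates 1 and 2 there were 13 and 17 members higher and 6 and 4 lower, and without either vehicle array none was lower.

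Of 25 measured genes of the ER stress and amino acid response, 4 rose, 1 fell and 20 did not pass (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0027; adjusted p = 0.25 with an estimated correlation). Sdf2l1 and Hsp90b1, which help proteins fold in the endoplasmic reticulum, rose by 1.51 ± 0.15 and 0.84 ± 0.20 (log2, SE), and the phosphatase subunit Ppp1r15a by 1.30 ± 0.16. Phgdh, the entry enzyme of serine synthesis, fell by 0.85 ± 0.16. Hsp90b1 and Phgdh missed the threshold without vehicle replicate 1 (adjusted p = 0.37 and 0.14), without vehicle replicate 2 (0.36 and 0.099) and without the intensity trend (0.14 and 0.10). Members higher numbered 2 without either vehicle array, 14 without IL-1b replicate 1 and 11 without IL-1b replicate 2, and members lower 0, 2 and 5.

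Among 15 measured lipid efflux and scavenger receptor genes, 3 rose, 3 fell and 9 did not pass (5 and 3 adjusted over the list alone, camera adjusted p = 0.36). The list's median of 0.21 and mean of -0.05 differed in sign. The median was 0.45 without vehicle replicate 2, and 0.18 to 0.30 without each other array. The lipoprotein receptor Vldlr fell by 3.18 ± 0.19 and the sterol transporter Abcg4 by 2.84 ± 0.57, while the fatty acid carrier Fabp5 rose by 2.47 ± 0.15 and the lipid droplet protein Plin2 by 1.22 ± 0.17 (log2, SE). Abcg4, above background on 1 of the 2 IL-1b arrays, had a log2 fold change of -2.05 and -3.63 without IL-1b replicates 1 and 2, missed the threshold without vehicle replicate 2 (adjusted p = 0.14), and, with Plin2, without the intensity trend (0.081 and 0.067). Members higher numbered 6 and 5 without IL-1b replicates 1 and 2 and 2 without either vehicle array, and members lower 1 without vehicle replicate 2. Of 20 measured cholesterol synthesis genes, 2 fell, 0 rose and 18 did not pass, the same adjusted over the list alone (camera adjusted p = 0.27). These were Pmvk at -1.01 ± 0.19 and Idi1 at -0.71 ± 0.17, neither of which passed without vehicle replicate 1 (adjusted p = 0.18 and 0.29), vehicle replicate 2 (0.074 and 0.18) or the intensity trend (0.069 and 0.16). Without IL-1b replicates 1 and 2 there were 4 and 5 lower and 1 and 2 higher.

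Vascular receptors and ion channels had 3 of 26 measured members higher, 6 lower and 17 not past the threshold (3 and 10 adjusted over the list alone), and the list was at the edge of the threshold (camera adjusted p = 0.051). It passed under quantile normalization (adjusted p = 0.028) and without IL-1b replicate 1 (0.021). Besides Npr3, Rgs4, which shortens G protein signals, fell by 4.36 ± 0.14, while the nucleotide receptors P2ry2 and P2ry6 rose by 3.59 ± 0.29 and 2.50 ± 0.21 (log2, SE). The list's median log2 fold change of -0.57 was -0.27 over 46 members with no filter on dim probe sets. Members lower numbered 11 without either IL-1b array. In the growth factor and TGF-beta list, 10 of 45 measured members rose, 8 fell and 27 did not pass (14 and 10 adjusted over the list alone; camera adjusted p = 0.39), and camera put the list higher and fry lower. The activin subunit Inhbb fell by 4.37 ± 0.33, the receptor Fgfr2 by 3.62 ± 0.25 and Tgfb3 by 2.90 ± 0.16, while Bmp6 rose by 3.40 ± 0.17. Inhbb was above background on 1 of the 2 IL-1b arrays. Without IL-1b replicates 1 and 2 the members higher numbered 17 and 19 and the members lower 11 and 14. Of 13 measured osteochondrogenic genes, 4 rose, 2 fell and 7 did not pass (5 and 4 adjusted over the list alone; camera adjusted p = 0.39). Their median log2 fold change was 0.65, and 0.087 over 23 members with no filter on dim probe sets. The phosphate transporter Slc20a1 rose by 1.86 ± 0.14 and the pyrophosphate-generating enzyme Enpp1 by 1.16 ± 0.27, while the parathyroid hormone receptor Pth1r fell by 2.76 ± 0.45 and Bmp4 by 1.46 ± 0.18. Pth1r, above background on 1 of the 2 IL-1b arrays, was at -2.09 and -3.42 without IL-1b replicates 1 and 2. Enpp1 missed the threshold without vehicle replicate 2 (adjusted p = 0.12), and without the intensity trend Enpp1, Pth1r and Bmp4 had adjusted p values of 0.13, 0.064 and 0.053. The list's median of 0.65 was -0.06 without IL-1b replicate 1, where 4 members were higher and 5 lower, and without IL-1b replicate 2 the counts were 7 and 4. Without vehicle replicates 1 and 2, 2 members and 1 member were higher.

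Markers of other cells of the vessel wall and of blood were measured in the same samples. Of 6 measured macrophage and leukocyte markers, 1 rose, 0 fell and 5 did not pass (4 rose adjusted over the list alone). The 1 that rose was Lyz2, lysozyme, at least 28.96-fold, from 7.03 ± 4.52 to 827 ± 201 (SD, n = 2, adjusted p = 2.2e-04). Cd14 and Cd74 had log2 fold changes of 0.54 and 0.60 (adjusted p = 0.072 and 0.12). The list passed (camera adjusted p = 0.010), with an adjusted p of 0.25 with an estimated correlation and 0.063 with no filter on dim probe sets. Without IL-1b replicates 1 and 2 the members higher numbered 3 and 5. Of 5 endothelial markers measured, 1 fell, 0 rose and 4 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.87). The 1 that fell was the transcription factor Erg, at -2.57 ± 0.46 (log2, SE), which was above background on 1 of the 2 IL-1b arrays and missed the threshold without vehicle replicates 1 and 2 (adjusted p = 0.14 and 0.34). The endothelial median of -0.22 was 0.14 without IL-1b replicate 2 and -0.57 without IL-1b replicate 1. Without vehicle replicates 1 and 2 it was -0.38 and -0.05. With no filter on dim probe sets the endothelial median was 0.28, over 16 markers. Of 10 measured adventitial fibroblast markers, 2 rose, 1 fell and 7 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.39). Dpt (dermatopontin), above background on 1 of the 2 vehicle arrays, rose by 3.34 ± 0.38 and Pdgfra by 1.80 ± 0.41, and Col14a1 fell by 1.22 ± 0.14. Pdgfra missed the threshold without vehicle replicates 1 and 2 (adjusted p = 0.16 and 0.077). Without IL-1b replicate 1 or 2, 4 of these fibroblast markers were higher, and without either vehicle array 1 was. Of 2 measured nerve and adipose markers, the adhesion molecule Ncam1 fell by 1.64 ± 0.22, and the list was too small to test. Of 12 measured housekeeping genes, 1 rose, 0 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.39). The 1 that rose was the transferrin receptor Tfrc, at 0.86 ± 0.14, which missed the threshold without vehicle replicates 1 and 2 (adjusted p = 0.096 and 0.093) and without the intensity trend (0.084). The housekeeping median was 0.10, 0.02 under quantile normalization and -0.07 without IL-1b replicate 1, where 3 of them were higher and 4 lower, and without IL-1b replicate 2 the counts were 6 and 2.

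Of the 26 lists tested with the preset correlation, 14 passed, 11 higher and 3 lower. With a correlation estimated from these 4 arrays camera called 0 lists, 6 lists had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 17. Groups of 2 and 2 arrays allow no exact permutation p below 0.333 for a single value, so single values per array are given without a test.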

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

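The tests of the control probe sets in this part were chosen after the result was seen. The hybridisation controls of IL-1b replicate 1, measured outside the comparison of genes, read 3.50 times their mean on the vehicle arrays, and all 18 of these probe sets were above their mean on the other 3 arrays. If more control transcript had been added to this sample, control probe sets for bacterial transcripts that read dim on every array would have stayed level. Their median was 2.66 times the vehicle arrays, against 1.10 times on IL-1b replicate 2, and 23 of 27 were above their mean on the other arrays, which argues against that explanation as the whole cause. The same value of 2.66 is consistent with weaker signal of the sample on this array, scaled up together with its background. No biological explanation was tested, and how far a larger share of a few very bright transcripts adds to it stays open.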

How the results depend on the processing

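All probe sets past the threshold kept their direction under every alternative that tested them. This was largely fixed in advance. Changing the filter, trend, prior, block or centring left the log2 fold changes correlated at 1 with the main ones. In the 1532 genes past the threshold the groups did not overlap, so leaving out 1 array could not reverse them. Under quantile normalization, which could, all 2500 probe sets tested kept their sign. Of the 111 genes named by the fixed rule that passed, 82 passed under every alternative and 29 missed the threshold under at least 1. Genes named after their values were seen are not in this count. Without the intensity trend 963 probe sets passed (484 higher, 479 lower) and 576 genes (297 higher, 279 lower), and 915 of those probe sets were among the 2503; the alternative shares 1 prior spread over all intensities. At an adjusted p under 0.01, 1222 probe sets passed (595 higher, 627 lower). Leaving out each array in turn gave 1357 to 8666 probe sets, 699 to 4137 higher and 658 to 4529 lower, and 824 to 4996 genes, 425 to 2282 higher and 399 to 2714 lower. Fewer passed without a vehicle array (1417 and 1310 of the 2503 remained without vehicle replicates 1 and 2) and more without an IL-1b array (2501 and 2503 remained), because the spread then came from the other pair alone. The SD of the log2 difference between replicates was 0.432 for vehicle and 0.757 for IL-1b. Lists past the threshold numbered 12 to 17 under the other alternatives, 13 to 15 with an array left out, and 0 in camera with an estimated correlation, for which 6 lists had an unadjusted p under 0.05. The estimated correlation was below the preset 0.01 for NF-kB (0.0059), cytokines (-0.025), prostanoid synthesis (-0.044) and complement (-0.026). The same held for adhesion molecules, matrix proteases, ER stress and leukocyte markers. A larger correlation therefore did not remove these calls. The estimate was above 0.01 for the contractile list, chemokines, cell cycle, interferon response, oxidative stress and glycolysis. With an estimated correlation camera judged each list on the fit's 2 residual degrees of freedom. With the preset correlation it used many more, set by the number of genes. The loss of all calls therefore says little about any 1 list. How much the larger estimates added to the loss was not tested.

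With an estimated correlation the adjusted p was 0.18 for cytokines, NF-kB, prostanoid and nitric oxide synthesis, interferon response, complement and acute phase, and oxidative stress. It was 0.25 for the contractile list, chemokines, adhesion molecules, matrix proteases, cell cycle, ER stress, and macrophage and leukocyte markers, and 0.27 for glycolysis and hypoxia. Matrix proteases also missed the threshold with no offset (0.054), with the filter at the 60th percentile (0.23) and without the trend (0.086), and passed at 0.046. Lists that gained a call were IL-1 receptor signalling by fry (0.018) and with the block (0.0097), adventitial fibroblast markers by fry (0.013), and vascular receptors by fry (0.0047), with the block (0.012), with the offset at the 25th percentile (0.046) and without the trend (0.047). Col1a1 reversed to -0.12 under quantile normalization and without IL-1b replicate 1, and passed at 0.58 without IL-1b replicate 2; the cause was not tested. Scaling moved the median of all probe sets tested by less than 0.1, from 0.015 to -0.028 under quantile normalization and to 0.0032 under median centring.

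With the replicate number as a block 3276 probe sets passed, and 16 lists. Differences between replicates 1 and 2 correlated at r = 0.091 between the groups over probe sets, and 2 pairs without a stated link leave the samples sharing only a number. Where signal was near background (54.2% of probe sets lay above it on IL-1b replicate 1 and 72.3% on IL-1b replicate 2) changes of dim genes have only bounds.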

Other observations

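The gene groups in the next 2 paragraphs were put together after their values were seen, so their counts describe these samples and are no test of a theme. Of 8 measured genes of caveolae, the membrane pits that are dense in smooth muscle, 5 fell, 0 rose and 3 did not pass. Cavin2 had a log2 fold change of -3.93 (adjusted p = 3.3e-04, 1 of the 2 IL-1b arrays above background), Cav2 of -2.92 and Cav3, the muscle caveolin, of -2.27. Of 9 measured small leucine-rich proteoglycans, which bind collagen fibrils, 6 fell and 3 did not pass, with Omd falling by 4.49, Aspn, above background on 1 of the 2 IL-1b arrays, by 3.28 and Fmod by 2.18. Of 4 vascular gap junction genes, Gja5 rose by 3.91, Gja4 fell by 2.58 (-1.91 and -3.24 without IL-1b replicates 1 and 2), and Gja1 had values of 12442 ± 543 and 11344 ± 884 (SD, n = 2, adjusted p = 0.70).

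Of 9 measured cell surface genes of coagulation and fibrinolysis, 3 rose, 2 fell and 4 did not pass. Plat rose by 4.42 (3.83 and 5.01 without IL-1b replicates 1 and 2), while Thbd (thrombomodulin), which turns thrombin into an anticoagulant, fell from 5115 ± 91.2 to 610 ± 132 (SD, n = 2) and F3 fell by 1.21. Of 22 measured targets and regulators of hypoxia-inducible factors, 7 rose, 4 fell and 11 did not pass. Egln3, above background on 1 of the 2 vehicle arrays, rose by 6.89 and Epas1 (HIF-2 alpha) by 2.68, while Car9 (carbonic anhydrase 9) fell by 3.14, Hilpda from 1402 ± 83.3 to 295 ± 45.4, and Ankrd37 at least 3.04-fold, from 115 ± 3.42 to 10.5 ± 7.21 (adjusted p = 0.031). Of 146 families of gene symbols with the same leading letters, camera called only the Ccl chemokines (adjusted p = 4.4e-04; adjusted p = 0.98 with an estimated correlation).

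The test of the interferon list on IL-1b replicate 2 alone was chosen after the result was seen, and the test of scaling before. Of 33 measured interferon response genes, 23 fell and 10 did not pass, and the list did not pass with an estimated correlation (adjusted p = 0.18). The array that stands apart is not the sole source, since the median log2 change of the 33 measured members was -1.42 on IL-1b replicate 2 alone. There 97.0% of the members lay below both vehicle arrays, where chance gives 33.3%. That share was largely fixed, because the threshold nearly requires it of the 23 members that passed. Scaling between arrays is argued against as the whole cause, since the count of members lower past the threshold was 22 under quantile normalization and 25 under median centring, against 23. No biological explanation is weighed here, and the cause stays open.

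A further pattern is the rise of Lyz2, the 1 of 6 macrophage and leukocyte markers past the threshold, whose list did not pass with an estimated correlation (adjusted p = 0.25) or with no filter (0.063). More leukocytes in the IL-1b cultures would bring their shared transcripts, and of 8 such genes (Ptprc, Cd53, Coro1a, Laptm5, Tyrobp, Fcer1g, Itgam and Aif1) 1, Cd53, was above background on both IL-1b arrays and higher by at least 1 on the log2 scale, the outcome set in advance as evidence against leukocytes. That outcome decides nothing, because only 2 of the 8, Cd53 and Fcer1g, were above background on both IL-1b arrays, and genes near the floor cannot exclude a small number of cells. Only Tyrobp was lower, at -0.65 (log2), and every other probe set of these genes was higher. The largest change was 1.71 for 1 of the probe sets of Ptprc, which read 94.9 on IL-1b replicate 1 and 6.41 on IL-1b replicate 2. Background was itself higher on IL-1b replicate 1, at 76.7 against 18.8 on IL-1b replicate 2. Leukocytes and expression by the smooth muscle cells both stay open as the source of Lyz2.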
